A study of Mus musculus with 24 samples.

How the data were processed

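RNA was measured in cerebral cortex of heterozygous mice carrying eGFP-tagged ribosomal protein L10a under the Aldh1l1 promoter. The bound fraction was hybridized from 18 single animals (6 in sleep, 6 in waking, 6 after sleep deprivation), and the unbound fraction from 6 pools of 3 animals, 2 per state (animals 1 to 3 and 4 to 6). Per the labels, sleeping mice were killed between 3 and 5 pm after a sleep bout of more than 45 min and at least 75% sleep in the previous 6 to 7 h, waking mice between 3 and 5 am after a bout of more than 1 h, and sleep-deprived mice after 4 h with unfamiliar objects in the light phase. The arrays were Affymetrix mouse genome chips with 45101 probe sets.

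The deposited values were log2 RMA values (background-corrected, quantile-normalized, summarised per probe set) per the submitters' processing notes, with the version not given in the sources used here. Which arrays were normalized together was not stated. The table held 45101 probe sets without missing values. After 64 control probe sets were left out, 34945 probe sets paired with 1 gene symbol in the array annotation, 932 with several and 9160 with none, and the last 2 kinds were left out of the gene-level tests. Of those with 1 symbol, 34741 had an Entrez ID in the RefSeq table, and 18193 genes were tested, each by the probe set with the highest mean over the 24 arrays (9183 genes had 1 probe set, 9010 had 2 or more).

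Linear models with empirical Bayes moderation were fitted in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p under 0.05 as threshold. State comparisons used the 18 bound or the 6 unbound arrays, and the comparison of fractions and the differences of state effects between fractions used all 24 arrays in 6 groups. Genes past the threshold with the same sign in waking and in sleep deprivation against sleep were counted, and the count was set beside divisions of the shared sleep arrays, and the correlation of the log2 differences beside simulated groups without effects. Fixed gene lists were tested with camera at a preset correlation of 0.01, adjusted over 31 lists per comparison, with an estimated correlation as alternative. For each list, p-values were also adjusted over its members alone. A gene was called dim or bright by its mean log2 level over the arrays of the fit, below or at least at the median of all probe sets (5.79 for bound, 5.64 for unbound arrays). The lists, comparisons, tests, thresholds and the rule for named genes were chosen before the data were examined. The rule allowed the 10 genes with the largest positive and the 10 with the largest negative difference among those past the threshold in each comparison (for genes changed alike, ranked by the smaller of the 2 differences, with unnamed and predicted transcripts skipped), members of the lists, and always Aldh1l1 and Rpl10a. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.

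The main models had no block. Whether replicate numbers pair the animals was checked by correlating residuals of arrays with the same number in different states. The 18 bound pairs gave 0.256 to 0.493, and -0.089 to 0.148 after the difference between animals 1 to 3 and 4 to 6 had been removed, with the own number the best match in 9 of 18. The unbound pools gave 0.015 to 0.021. Alternatives were the replicate number or pool as a block, a filter on dim genes, the mean of the probe sets of a gene, every probe set, repeated quantile normalization, centring of arrays, an intensity trend, array weights, a limit of 1.5-fold, bound-enriched genes only, other sets of arrays for the spread, and each array left out in turn. Alternatives that used animals 1 to 3 and 4 to 6 of the bound arrays, or several of these choices together, such as a block and an estimated correlation in camera, were added after the data had been seen.

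The number of arrays limits precision. On simulated data with the spread of these arrays, the bound waking comparison recovered 19.4%, 67.8% and 95.5% of changes of 0.5, 1 and 2 log2 units (13 of 148 calls false). The unbound comparison recovered 0%, 2.99% and 66.7% (1 of 47), and the fraction comparison 50.7%, 85.1% and 97.0% (6 of 161). For the difference between fractions the shares were 0%, 23.9% and 66.7% (2 of 62). In the bound waking simulation camera found the 1 list that had been shifted, by 1 log2 unit in every member. The simulated genes varied independently of each other, so this is no check of the preset correlation in camera. The false calls given above are counts from simulated data. They give no rate for the real arrays, where offsets between groups could add calls if RMA was run separately for each group. No array was left out. Genes on the Y chromosome and Xist were not examined.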

Results

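Transcripts of cortical astrocytes were compared between 3 vigilance states of the mouse. The animals expressed ribosomal protein L10a fused to eGFP under the Aldh1l1 promoter, which is active in astrocytes. The immunoprecipitated ribosomes gave the bound fraction, meant to carry astrocyte mRNA, and the supernatant gave the unbound fraction. Sleeping mice (6) and sleep-deprived mice (6, kept awake for 4 h with unfamiliar objects) were killed in the light phase, and spontaneously waking mice (6) in the dark phase. Each of the 18 bound samples came from 1 animal, and each of the 6 unbound samples was a pool of 3 animals of 1 state (animals 1 to 3 or 4 to 6). The fractions were compared to see which transcripts the pull-down enriched, and the states to see which transcripts differed between sleep and wakefulness. Waking also differed in time of day from sleep and from sleep deprivation. Genes changed alike by waking and by sleep deprivation against sleep were therefore counted as well. The median log2 difference of all genes was 0.09 for bound waking against sleep, 0.11 for bound sleep deprivation against sleep, 0.02 for bound sleep deprivation against waking and 0.16 for bound against unbound. It was 0.30, 0.18 and -0.12 in the corresponding unbound comparisons, and -0.22 and -0.06 for the differences between fractions in the effects of waking and of sleep deprivation. All log2 differences, folds and list medians below are given relative to these medians, with the standard error (SE) of the fit. Adjusted p and the counts of genes past a test, as higher (rose) or lower (fell), rest on the differences as fitted, before these medians were taken off. Exactly tied values occurred within groups but in none of 228 pairs of arrays from different groups, so RMA may have been run separately for each group. State and fraction would then coincide with run. Adjusted p rests on the spread within groups and would not cover offsets between runs, so the counts below can include such offsets.

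The bound fraction was enriched in astrocyte transcripts and poor in neuronal ones. Aldh1l1, whose promoter drove the transgene, was 13.2-fold higher in bound than in unbound samples (log2 3.72 ± 0.11, adjusted p = 7.44e-18), at 10.90 ± 0.25 (SD, n = 18) against 7.02 ± 0.17 (SD, n = 6), and lay above the unbound mean in 18 of 18 bound arrays. Rpl10a, the gene of the tagged ribosomal protein, was 2.24-fold higher (log2 1.17 ± 0.18, adjusted p = 1.5e-06). Among the largest enrichments were Lfng, a glycosyltransferase acting on Notch (log2 5.86 ± 0.60), Ppp1r3g, a subunit that targets protein phosphatase 1 to glycogen (5.36 ± 0.22), and the lipid carrier Apoe (4.94 ± 0.41). The largest depletions included the long non-coding RNAs Meg3 (-5.05 ± 0.47) and Miat (-4.11 ± 0.35), the mitochondrially encoded ND5 (-4.73 ± 0.36) and the presynaptic scaffold gene Pclo (-4.44 ± 0.42). Some sizes varied with the processing, though no call was lost. As fitted, log2 ran from 4.66 to 6.47 for Lfng, -5.15 to -2.48 for Meg3 and -4.46 to -2.06 for Miat. In bound animals 4 to 6 minus 1 to 3, compared after the data had been seen, it was -2.69 for Lfng and 1.98 for Meg3.

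All 26 astrocyte markers passed the test as higher in the bound fraction, 26 of them also adjusted over the list alone, with a median log2 difference of 3.26 (camera adjusted p = 1.1e-16, and adjusted p = 1.32e-05 with an estimated correlation). The gap junction gene Gjb6 was 16.5-fold, the water channel gene Aqp4 10.2-fold and the glutamate transporter gene Slc1a3 8.57-fold higher. The glutamate transporter gene Slc1a2 was 1.98-fold higher and the glutamine synthetase gene Glul 2.18-fold. Of 24 neuron markers, 21 were lower and 3 did not pass (21 adjusted over the list alone; median -2.21; camera adjusted p = 6.53e-11, and adjusted p = 0.00326 with an estimated correlation). Among the lower ones were the chloride transporter gene Slc12a5 (log2 -2.95 ± 0.15) and Nefm, which encodes a neurofilament (-3.36 ± 0.21). Of 16 oligodendrocyte markers, 11 were lower and 3 higher (11 and 4 adjusted over the list alone; camera adjusted p = 0.0021, lost at adjusted p = 0.0604 with an estimated correlation). The myelin genes Mag (-2.76 ± 0.16) and Mbp (-2.11 ± 0.15) were lower, and the transcription factor genes Olig2 (2.56 ± 0.28) and Olig1 (1.77 ± 0.13) were higher. Microglia markers were lower in 10 and higher in 2 of 15 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.0065, lost at adjusted p = 0.074 with an estimated correlation). Meningeal and fibroblast markers were higher in 9 of 10 cases, 9 adjusted over the list alone (camera adjusted p = 0.0102, lost at adjusted p = 0.331 with an estimated correlation). Ependymal and choroid plexus markers were higher in 4 of 11 cases and lower in none, also adjusted over the list alone, with all 11 above the median gene (median 1.27 against 1.14 for the meningeal list; camera adjusted p = 0.148). The lists of oligodendrocyte precursor, endothelial, pericyte and smooth muscle, and red blood cell markers did not pass camera.

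**Figure D1:**
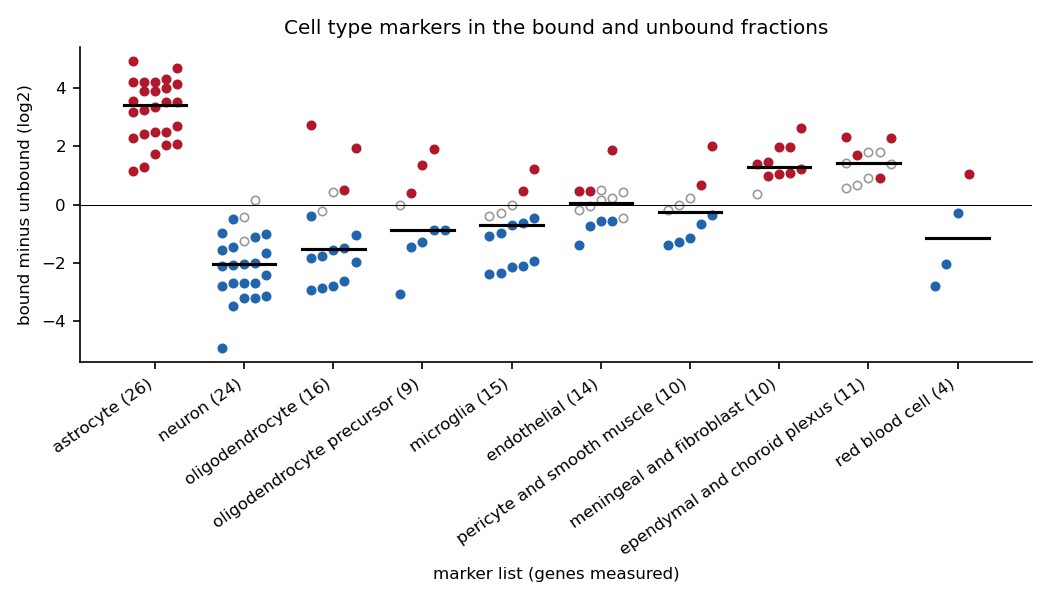
Bound minus unbound log2 difference, as fitted, of every measured marker in 10 cell type lists; each point is 1 gene (red, higher; blue, lower; open, not past the test) and each bar the list median, with the number of genes measured in brackets. All 26 astrocyte markers lie above 0, and 21 of 24 neuron markers are lower past the test.

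Several lists of metabolic and homeostatic genes were higher in the bound fraction as well, but that of glycolysis and lactate transport was not (8 of 18 higher and 3 lower, also adjusted over the list alone; median -0.12; camera adjusted p = 0.55). Genes of fatty acid oxidation and lipid droplets were higher in 19 of 20 cases (19 adjusted over the list alone; median 2.31; camera adjusted p = 8.62e-11, and adjusted p = 0.000106 with an estimated correlation). Genes of glycogen metabolism were higher in 17 of 20, with 1 lower (17 and 2 adjusted over the list alone; camera adjusted p = 1.31e-05, and adjusted p = 0.000495 with an estimated correlation). Potassium, water and pH homeostasis and gap junction genes were higher in 16 and lower in 2 of 18 cases (camera adjusted p = 1.24e-07, and adjusted p = 0.000266 with an estimated correlation). Aqp4, Atp1b2, Gja1, Gjb6, Slc4a4 and Mlc1 are also astrocyte markers, so this result partly repeats that of the astrocyte list. The glycogen list shares Ppp1r3c with it. Cholesterol biosynthesis genes were higher in 17 and lower in 1 of 20 (camera adjusted p = 0.000138, lost at adjusted p = 0.129 with an estimated correlation). Cytosolic heat shock chaperones went both ways, with 12 lower, such as Hsph1 (log2 -2.03 ± 0.15), and 5 higher, such as the co-chaperone gene Bag3 (2.69 ± 0.16), of 19 (camera adjusted p = 0.0455, lost at adjusted p = 0.331 with an estimated correlation). In the last 3 of these lists the counts adjusted over the list alone equalled those over all genes. Over all genes, 7672 were higher and 4955 lower in the bound fraction at an adjusted p under 0.05, of 18193 tested, and 16 of 31 lists passed camera, 10 of them with an estimated correlation.

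In the bound fraction, waking went with higher levels of several immediate early genes, which are induced within minutes of stimulation of a cell. Egr2, a zinc finger transcription factor gene, was 5.88-fold higher in waking than in sleep (log2 2.56 ± 0.55, adjusted p = 0.00361), from a dim sleep level of 4.44 ± 1.02 (SD, n = 6). Arc, known for its role at neuronal synapses, was 4.68-fold higher (log2 2.23 ± 0.34, adjusted p = 0.000239), at 8.34 ± 0.57 (SD, n = 6) against 6.02 ± 0.62 (SD, n = 6), and Nr4a1, which encodes an orphan nuclear receptor, 3.41-fold (1.77 ± 0.27, adjusted p = 0.000228). Cirbp, the gene of the cold-inducible RNA-binding protein, was 3.54-fold lower (log2 -1.83 ± 0.17, adjusted p = 5.71e-06). Each of these differences was seen in 6 of 6 waking arrays against the sleep mean.

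By list, 10 of 20 immediate early genes rose and none fell (13 adjusted over the list alone; median 0.60; camera adjusted p = 2.21e-05, lost at adjusted p = 0.423 with an estimated correlation). These included Fos (2.13-fold), Dusp1, which encodes a phosphatase of MAP kinases (1.63-fold), and Homer1, which encodes a postsynaptic scaffold protein (1.5-fold). Of 11 clock genes of the negative limb and their outputs, 2 fell, also adjusted over the list alone, and 9 did not pass. The 2 were Ciart (log2 -1.83 ± 0.43, adjusted p = 0.0131) and Dbp (-0.92 ± 0.17, adjusted p = 0.0028), both outputs of the circadian clock (camera adjusted p = 0.0384, lost at adjusted p = 0.755 with an estimated correlation). Of 7 clock genes with the opposite phase, Npas2 rose (1.46-fold), 1 also adjusted over the list alone. Endoplasmic reticulum chaperones rose in 5 of 18 cases (6 adjusted over the list alone; camera adjusted p = 0.0452, lost at adjusted p = 0.755 with an estimated correlation). They were Xbp1, a transcription factor gene of the unfolded protein response (1.79-fold), Creld2 (1.65-fold), Sdf2l1, Manf and Dnajc3. Hspa5, the gene of the chaperone BiP, was 1.43-fold higher without passing (adjusted p = 0.0716), but passed in 7 of 30 alternatives. Of 20 cholesterol biosynthesis genes, only Idi1 fell (log2 -0.50 ± 0.11), 1 also adjusted over the list alone (camera adjusted p = 0.0452, lost at adjusted p = 0.755 with an estimated correlation).

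Of 26 astrocyte markers, 3 rose in waking, also adjusted over the list alone, and 23 did not pass. The 3 were the connexin 30 gene Gjb6 (1.42-fold, adjusted p = 0.00061), Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1 (1.29-fold, adjusted p = 0.000757), and the growth factor receptor gene Fgfr3 (1.2-fold). Of 32 actin cytoskeleton genes, 2 fell and 1 rose (1 and 1 adjusted over the list alone). The cytoplasmic actin genes Actg1 (log2 -0.47 ± 0.08) and Actb (-0.31 ± 0.07) fell, and stayed lower under each scaling tried, but the call for Actb (adjusted p = 0.046) was lost in 22 of 31 alternatives. Among markers of other cells that rose were the interneuron peptide gene Vip (1.73-fold), the oligodendrocyte gene Ermn (2.08-fold) and the microglia gene Tmem119 (1.98-fold). In these lists 1 of 24 neuron, 2 of 16 oligodendrocyte and 3 of 15 microglia markers rose and none fell, with the same counts adjusted over the list alone. Elsewhere 1 of 9 oligodendrocyte precursor, 2 of 14 endothelial, 2 of 10 pericyte and smooth muscle and 1 of 4 red blood cell markers rose (2, 2, 2 and 2 adjusted over the list alone), and 1 pericyte and smooth muscle marker fell.

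Among the calls named here, the one for Sdf2l1 was lost in 16 of 31 alternatives, Homer1 in 14 of 30, Manf in 10 of 31, Npas2 in 10 of 30, and Fgfr3 and Idi1 in 6 of 31 each. In all, 2039 of 18193 genes differed between waking and sleep in the bound fraction, 1650 higher (80.9%) and 389 lower, and 4 of 31 lists passed camera. With quantile normalization repeated, 742 genes were higher and 633 lower. With the replicate number as a block 3064 differed, and with genes below the median level left out 142. With array 1 or 3 of sleep or array 5 of waking left out, 1 list passed, the immediate early genes, and 2 passed without array 2 of sleep or array 1, 4 or 6 of waking.

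After sleep deprivation the lists of immediate early genes and of genes that respond to glucocorticoids lay higher, both lost at adjusted p = 0.174 with an estimated correlation. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, was 7.31-fold higher than in sleep (log2 2.87 ± 0.45, adjusted p = 0.000222), at 9.52 ± 1.36 (SD, n = 6) against 6.54 ± 0.20 (SD, n = 6). Cdkn1a, which encodes the cell cycle inhibitor p21, was 6.99-fold higher (2.80 ± 0.43, adjusted p = 0.00016). Hif3a, a hypoxia-inducible factor gene, was 5.94-fold higher (2.57 ± 0.30, adjusted p = 1.75e-05) and Arc 6.08-fold (2.60 ± 0.34, adjusted p = 4.46e-05). Tcim was 12.1-fold higher (log2 3.60 ± 0.60, adjusted p = 0.000381), from a dim sleep level of 4.92 ± 1.07 (SD, n = 6). Each of these was higher in 6 of 6 sleep-deprived arrays than the sleep mean. In animals 1 to 3 and animals 4 to 6, sets compared after the data had been seen, the log2 difference as fitted was 4.02 and 1.94 for Fkbp5, 4.01 and 1.82 for Cdkn1a and 5.33 and 2.10 for Tcim. The sets did not differ past the test in any of these 3 genes (adjusted p = 0.55, 0.303 and 0.55).

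Of 20 immediate early genes, 12 rose and none fell (14 adjusted over the list alone; median 0.92; camera adjusted p = 6.23e-07, lost at adjusted p = 0.174 with an estimated correlation). Among them were Egr2 (9.71-fold), Nr4a1 (4.5-fold), Fosb (4.44-fold) and Homer1 (2.08-fold). Of 22 glucocorticoid-responsive genes, 10 rose and none fell (12 adjusted over the list alone; median 0.45; camera adjusted p = 0.000118, lost at adjusted p = 0.174 with an estimated correlation). Beside Fkbp5 and Cdkn1a these included the sulfotransferase gene Sult1a1 (3.13-fold), the transcription factor gene Zbtb16 (3.77-fold) and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (2.33-fold). Clock genes of the negative limb went both ways. Per1 (2.20-fold) and Per2 (1.60-fold) rose, Dbp (log2 -1.05 ± 0.17) and Per3 (-0.73 ± 0.17) fell, and 7 of 11 did not pass (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0441 towards lower, lost at adjusted p = 0.56 with an estimated correlation). Cirbp fell 2.30-fold, and Npas2 rose 1.95-fold.

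Endoplasmic reticulum chaperones rose in 4 of 18 cases (4 adjusted over the list alone; camera adjusted p = 0.147), here with Hspa5 (1.48-fold). Heat shock chaperones rose in 3 of 19 (3 adjusted over the list alone; camera adjusted p = 0.147), among them Hsph1 (1.81-fold). In the fit with the replicate number as a block both of these lists passed (camera adjusted p = 0.0304 and 0.0144), and 7 of 31 lists in place of 4, but all 7 were lost with an estimated correlation in that fit (adjusted p = 0.363 for both of these lists), an alternative chosen after the data had been seen. Of 32 actin cytoskeleton genes, Actg1 (log2 -0.63 ± 0.08), Actb (-0.39 ± 0.07) and Cdc42ep4 (-0.56 ± 0.12) fell, the actin genes under each scaling tried. Synpo rose (0.78; 3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0984). Of 22 genes of translation initiation and RNA processing, 4 rose (4 adjusted over the list alone; camera adjusted p = 0.63), such as Rsrp1 (3.08-fold) and the splicing factor genes Tra2a and Srsf3. Gjb6 (1.5-fold) and Ppp1r3c (1.29-fold) were the 2 of 26 astrocyte markers that rose (2 adjusted over the list alone). Among markers of other cells, 1 of 15 microglia and 2 of 4 red blood cell markers rose and 2 of 14 endothelial markers fell, while 1 rose and 1 fell of 24 neuron and of 10 pericyte and smooth muscle markers. Adjusted over each list alone, 1 endothelial marker rose as well. No ependymal or choroid plexus marker passed singly, but the list of 11 lay lower (median -1.18; camera adjusted p = 0.0109, lost at adjusted p = 0.56 with an estimated correlation), and its mean level ranged from 6.20 to 8.97 among the 6 sleep arrays.

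Among the calls named here, the one for Srsf3 was lost in 12 of 30 alternatives, Hspa5 in 11 of 30, Per1 in 9 of 30 and Tra2a in 6 of 30. In all, 2597 genes differed between sleep deprivation and sleep in the bound fraction, 2230 higher (85.9%) and 367 lower. With quantile normalization repeated 964 were higher and 764 lower, and with genes below the median level left out 334 differed, 288 of them higher.

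**Figure D2:**
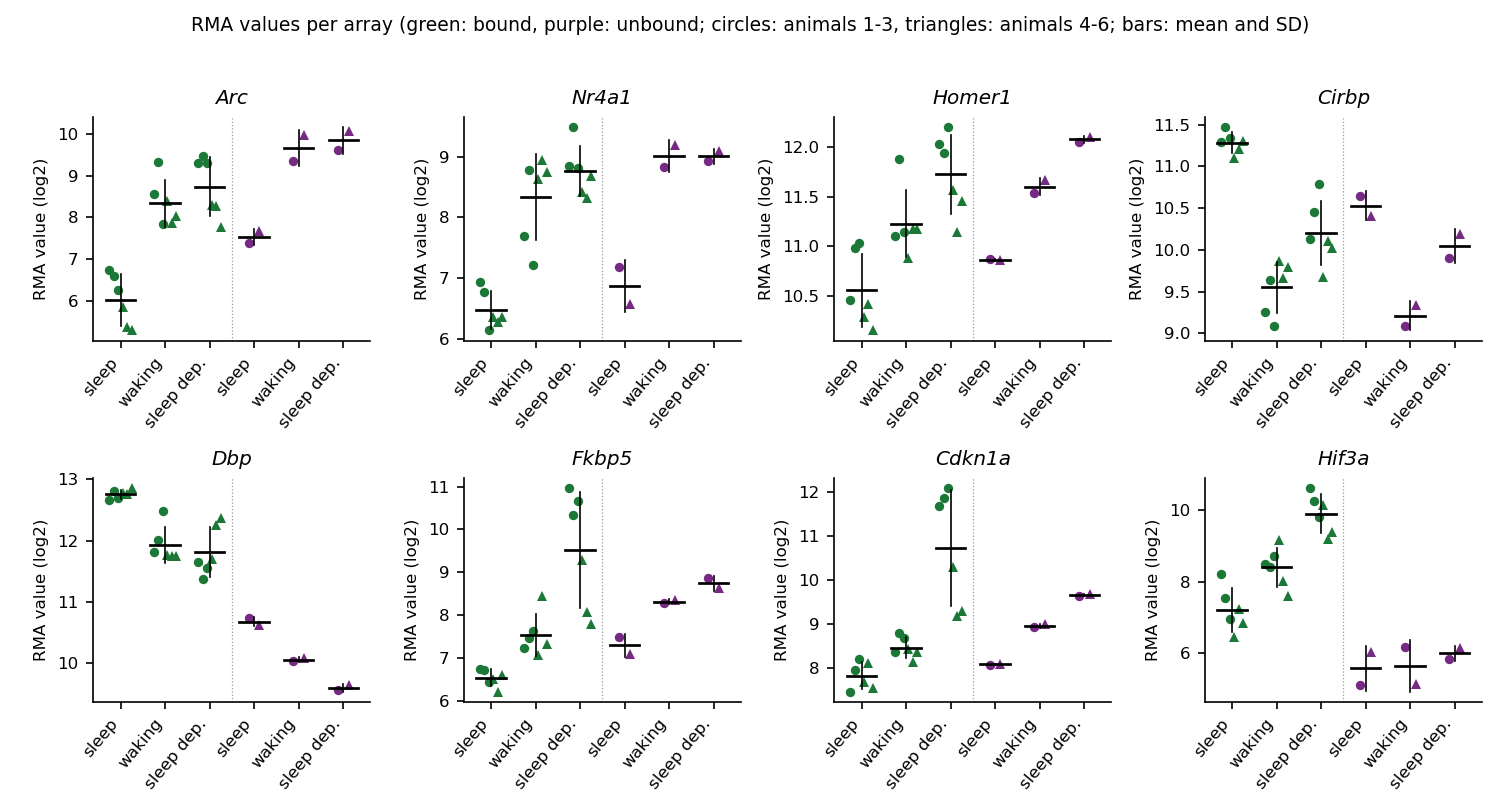
Log2 level of 8 genes in each array, by fraction and state; circles are animals 1 to 3, triangles animals 4 to 6, and bars the group mean with 1 SD (6 bound arrays or 2 unbound pools per state). Bound Arc lies at 6.02 ± 0.62 in sleep and 8.34 ± 0.57 in waking, without overlap.

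Between sleep deprivation and waking in the bound fraction 1 list passed camera, the glucocorticoid-responsive genes. It was lost at adjusted p = 0.201 with an estimated correlation. Sleep-deprived mice were killed in the light phase and waking mice in the dark phase. Time of day and sleep deprivation therefore cannot be told apart in this comparison. Cdkn1a was 4.77-fold higher after sleep deprivation than in waking (log2 2.25 ± 0.43, adjusted p = 0.00272) and Fkbp5 3.92-fold (1.97 ± 0.45, adjusted p = 0.0101), each in 6 of 6 arrays above the waking mean. In animals 1 to 3 and 4 to 6 the log2 difference as fitted was 3.27 and 1.29 for Cdkn1a and 3.22 and 0.77 for Fkbp5, and the call was lost in 1 of 30 alternatives for each. Emd, which encodes the nuclear envelope protein emerin, was 3.25-fold higher (1.70 ± 0.15, adjusted p = 5.32e-06). Of 22 glucocorticoid-responsive genes, 4 rose and none fell (9 adjusted over the list alone; median 0.44; camera adjusted p = 3.07e-05). The others were Nfkbia (1.53-fold), an inhibitor gene of NF-kappa-B, and the endothelin gene Edn1. Of 20 immediate early genes only Fosb rose (2.02-fold; 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.346). Cirbp was 1.54-fold higher after sleep deprivation than in waking, while Ermn (-0.93) and Tmem119 (-0.98) were lower, 1 of 16 oligodendrocyte and 1 of 15 microglia markers. So were 3 of 14 endothelial and 1 of 11 ependymal and choroid plexus markers, with the same counts adjusted over each list alone. Calls were lost for Ermn in 15 of 30 alternatives, Fosb in 13 of 30, Nfkbia in 8 of 31, Cirbp in 7 of 31 and Tmem119 in 7 of 30. In all 1244 genes differed, 759 higher and 485 lower, 1913 with the replicate number as a block and 76 with genes below the median level left out.

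Many genes differed from sleep in the same direction in waking and in sleep deprivation. Egr2, Arc, Nr4a1 and Maff, which encodes a small Maf transcription factor, rose in both comparisons, Maff 2.72-fold and 4.74-fold. So did Sult1a1 (2.13-fold and 3.13-fold), the RNA-processing gene Rsrp1 (2.36-fold and 3.08-fold), Gjb6 and Ppp1r3c. Cirbp, Dbp, Actb and Actg1 fell in both. At an adjusted p under 0.05 in each comparison 934 genes were higher and 125 lower in both, and 16 changed in opposite directions. With quantile normalization repeated 330 were higher and 259 lower, with the replicate number as a block 1656 changed alike, and with genes below the median level left out 70. Both comparisons used the same 6 sleep arrays. Independent lists of these sizes would share 202 higher and 7.85 lower genes. With the sleep arrays divided between the comparisons, 3 each, a mean of 171 genes over 20 divisions was higher and 18 lower in both, where independent lists of the sizes in each division would share a mean of 26.1 and 0.88, a value added after the data had been seen. In these divisions the log2 differences correlated at a mean of 0.296 (-0.052 to 0.365), lowest where the sleep arrays of animals 1 to 3 and 4 to 6 were parted. Without division the log2 differences correlated across genes, which are not independent replicates, at 0.595 against 0.502 in simulated groups without effects, with a covariance of 0.0751 against 0.0309, a difference of 0.0442. If RMA was run separately for each group, all 6 sleep arrays would share the offsets of 1 run. Dividing them would leave these offsets in both comparisons. Neither the independent lists nor the simulated groups hold such offsets, so an excess over them cannot be put down to vigilance state alone.

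**Figure D3:**
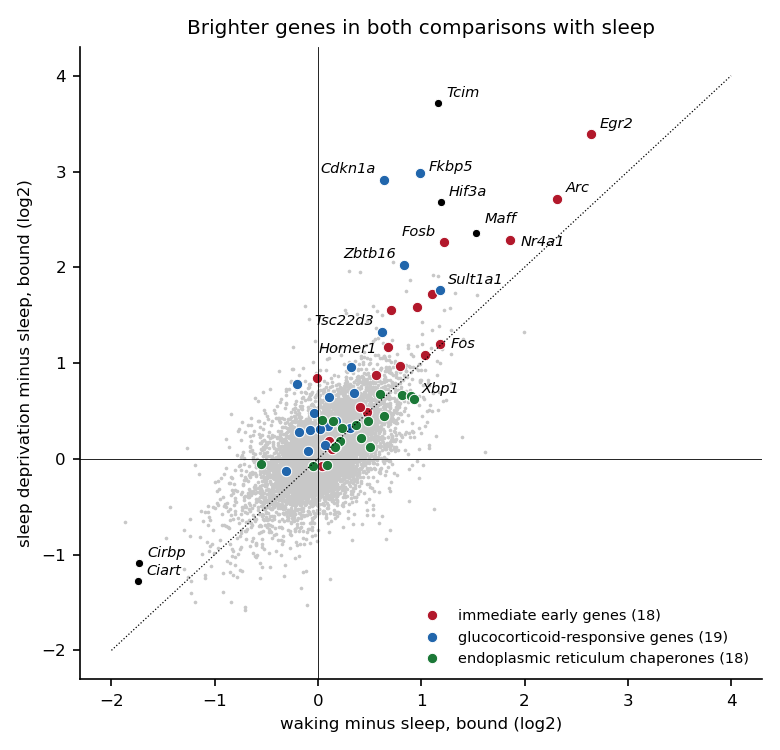
Log2 difference, as fitted, of waking minus sleep (x axis) and sleep deprivation minus sleep (y axis) in the bound fraction for genes at or above the median level, with members of 3 lists in colour and a dotted line of equality. Egr2 and Arc lie high on both axes, Fkbp5 and Cdkn1a mainly on the y axis.

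Most genes past the test were dim: 76.6% of those for waking against sleep, 70.9% for sleep deprivation against sleep and 79.6% for sleep deprivation against waking lay below the median level of all probe sets in the bound arrays. Of the genes named so far as changed between states, only Edn1 lay below it by its mean over all bound arrays. In the bound sleep arrays alone, the means of Egr2 (4.44), Tcim (4.92), Fosb (5.27) and Tmem119 (5.46) also lay below this median (5.79). Their folds against sleep are therefore measured from a dim level. A second probe set of a gene was then compared with the first, with directions taken relative to the median difference of probe sets at a similar mean level. Of genes called in the dimmer part that had another dim probe set, that probe set moved the same way in 48.3% (184 of 381, exact binomial 95% interval 43.2% to 53.4%) for waking against sleep and 51.3% (232 of 452, 46.6% to 56.0%) for sleep deprivation against sleep. In the brighter part the shares were 82.7% (134 of 162, 76.0% to 88.2%) and 83.4% (257 of 308, 78.8% to 87.4%). Among genes that were not called the shares were 53.6% and 54.0% in the dimmer and 63.1% and 64.0% in the brighter part. With the brighter genes alone, quantile normalization repeated and animals 1 to 3 or 4 to 6 as a block, together an alternative chosen after the data had been seen, 690 of 11616 genes differed between waking and sleep (338 higher, 352 lower) and 1005 between sleep deprivation and sleep (546 higher, 459 lower). In that fit endoplasmic reticulum chaperones (camera adjusted p = 5.24e-05 and 0.00236), heat shock chaperones (3.48e-05 and 0.00012) and clock genes of the positive limb (0.0331 and 0.00901) were higher in waking and in sleep deprivation than in sleep. With an estimated correlation in that fit all of these were lost (adjusted p = 0.0926 and 0.19, 0.0902 and 0.0962, and 0.213 and 0.139). Only the immediate early genes and the glucocorticoid-responsive genes then passed, both for sleep deprivation against sleep (adjusted p = 0.0262 for each).

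**Figure D4:**
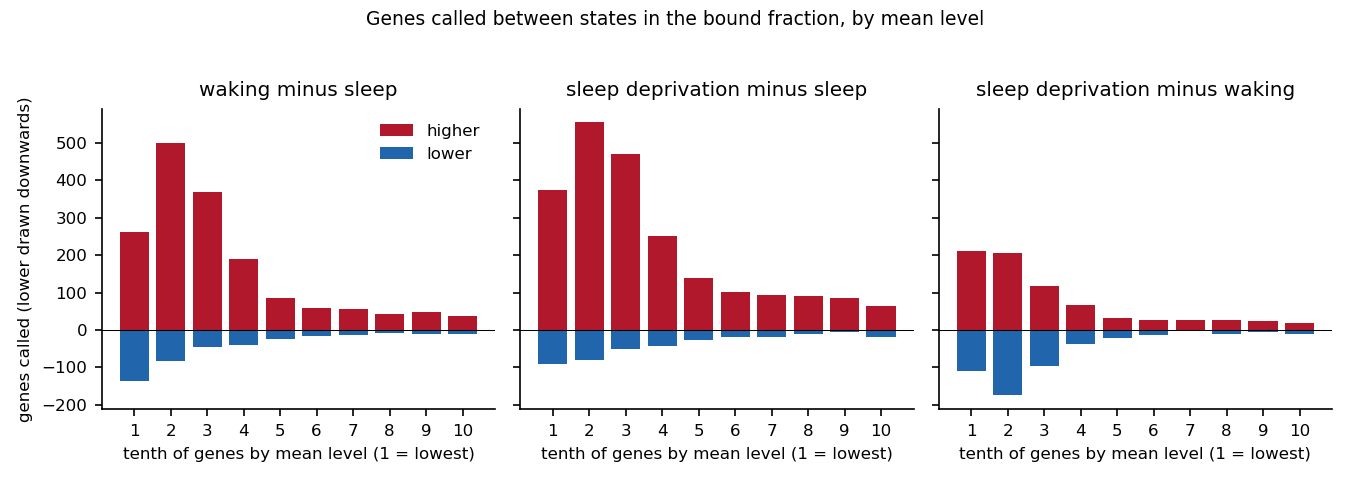
Number of genes higher (upward bars) and lower (downward bars) past the test in each of 10 equal parts of the genes, ordered by mean bound log2 level, for the 3 bound state comparisons. For waking against sleep, 501 higher and 84 lower genes lie in part 2, and 38 and 10 in the brightest part.

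In the unbound fraction waking again went with higher levels of several immediate early genes, together with several chaperones. Fos was 4.11-fold higher in waking than in sleep (log2 2.04 ± 0.29, adjusted p = 0.0308; 9.13 ± 0.40 (SD, n = 2) against 6.79 ± 0.39 (SD, n = 2)), and Arc 3.56-fold (1.83 ± 0.27, adjusted p = 0.0308). The chaperone gene Creld2 was 2.58-fold and Hspa5 1.58-fold higher, and Cirbp 3.07-fold lower, each in 2 of 2 pools. Of 20 immediate early genes 11 rose (12 adjusted over the list alone; camera adjusted p = 0.000169, lost at adjusted p = 0.833 with an estimated correlation). Of 18 endoplasmic reticulum chaperones 5 rose (13 adjusted over the list alone; camera adjusted p = 0.00125, lost at adjusted p = 0.833 with an estimated correlation). Of 19 heat shock chaperones 4 rose (14 adjusted over the list alone; camera adjusted p = 0.00129, lost at adjusted p = 0.833 with an estimated correlation), such as Ahsa1 (1.60-fold). Gjb6 (1.87-fold) and Ppp1r3c (2.09-fold) rose here too.

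After sleep deprivation unbound Fos was 5.53-fold higher than in sleep (log2 2.47 ± 0.29, adjusted p = 0.0374), Arc 4.41-fold, Cdkn1a 2.63-fold (adjusted p = 0.0371) and Fkbp5 2.42-fold (adjusted p = 0.0383), while Dbp was 2.39-fold lower, each in 2 of 2 pools. Of 20 immediate early genes 8 rose (13 adjusted over the list alone; camera adjusted p = 1.56e-05, lost at adjusted p = 0.913 with an estimated correlation). Of 22 glucocorticoid-responsive genes 3 rose (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0187, lost at adjusted p = 0.913 with an estimated correlation). Endoplasmic reticulum chaperones (camera adjusted p = 0.00366) and heat shock chaperones (0.0289) lay higher as lists, both lost at adjusted p = 0.913 with an estimated correlation. In them 1 of 18 and 0 of 19 members passed limma, and 9 and 7 were higher and 1 and 1 lower when adjusted over the list alone. Between sleep deprivation and waking the glucocorticoid-responsive genes lay higher (camera adjusted p = 0.00443, lost at adjusted p = 0.955 with an estimated correlation) though 0 of 22 passed limma singly, also adjusted over the list alone. The camera test for this list no longer passed without pool 1 of sleep deprivation.

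Over all genes, 1149 differed between waking and sleep in the unbound fraction (1039 higher, 110 lower), 341 between sleep deprivation and sleep (259 higher, 82 lower) and 138 between sleep deprivation and waking (44 higher, 94 lower), with 2 pools per state. These counts fell to 0 in limma with any 1 of the 6 pools left out and with the pool number as a block, while 5891, 4610 and 3818 genes had an unadjusted p under 0.05 in the fit without a block. With quantile normalization repeated 0, 134 (65 higher, 69 lower) and 2 (0 higher, 2 lower) passed.

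The difference of the state effects between fractions was tested directly. The response of Hif3a to sleep deprivation was larger in the bound than in the unbound fraction by a log2 of 2.33 ± 0.61 (adjusted p = 0.0343), and that of Tcim by 4.22 ± 1.13 (adjusted p = 0.0345). These calls were lost in 9 and 10 of 32 alternatives, with adjusted p up to 0.284 and 0.148, among them the fit with dim genes left out. With waking, the rises of Ppp1r3c (-0.68 ± 0.16, adjusted p = 0.00144) and Dusp1 (-0.84 ± 0.26, adjusted p = 0.0197) were smaller in the bound fraction, calls that were lost in 2 and 7 of 32 alternatives. For Arc the difference did not pass in either comparison (adjusted p = 0.927 and 0.876), nor for Fkbp5 (adjusted p = 0.386 after sleep deprivation). No list passed camera. In all 1018 genes differed between fractions in their response to waking (343 more positive and 675 more negative in bound) and 890 in their response to sleep deprivation (529 and 361), but with genes below the median level left out 37 and 22 did. For waking, 502 were more positive and 426 more negative with quantile normalization repeated, and 529 and 292 with arrays centred on their medians. The waking count was 502 without unbound sleep pool 1, 511 without sleep pool 2, 533 without waking pool 1 and 536 without waking pool 2. The sleep deprivation count was 447 and 485 without sleep pools 1 and 2 and 505 and 464 without sleep deprivation pools 1 and 2.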

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

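The tests of separate RMA runs and those of animals 1 to 3 against 4 to 6 were chosen after the result was seen; the split tests were set before, and so was the test of neuronal carry-over, except over genes chosen by their rise in unbound, which was added after the result was seen. Values are as fitted, but directions of second probe sets were taken relative to the median difference of probe sets at a similar mean level.

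Dim genes made up most of the calls in bound samples, and the 3 states differed in the median of all probe sets (5.69 in sleep, 5.82 in waking, 5.84 in sleep deprivation). Exactly tied values occurred in pairs of arrays of 1 bound group (52 to 240 per pair, 45 pairs) and of 1 unbound group (1707 to 2248, 3 pairs) but in none of 228 pairs from different groups, so RMA may have been run separately for each group, with an own offset of each probe set per run. The other dim probe set of a called dim gene moved the same way in 48.3% for waking and 51.3% for sleep deprivation against sleep, which goes with that explanation, although a dim probe set can also detect nothing. Among bright genes the shares were 82.7% (interval 76.0% to 88.2%) and 83.4% (78.8% to 87.4%). They argue against offsets that are independent between probe sets as the whole cause there. Whether probe sets of 1 gene share an offset was not tested, so separate runs with shared offsets stay open. The 63.1% and 64.0% of bright genes that were not called give no chance value, since called genes were picked by their difference. How much of each state difference stems from the runs stays open, since run and state coincide, and no biological explanation of the dim calls was tested.

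Bound arrays of animals 1 to 3 and 4 to 6 stood apart in every state, with 7972 genes differing between the sets (4159 higher and 3813 lower in animals 4 to 6). More carry-over of unbound RNA in animals 4 to 6 would lower all astrocyte markers together, but 8 were higher and 9 lower, which argues against it as the whole cause. As a part of the cause it stays open, since animals 4 to 6 correlated more closely with the unbound arrays (median 0.909 against 0.886), 11 neuron markers were higher and 5 lower, and the difference correlated at -0.356 with bound minus unbound. Loss of 5' ends would lower the 5' minus 3' difference of every control transcript: Gapdh fell from -0.361 to -1.0, but the 2 others moved the other way (Actb 0.210 to 0.306, Tfrc 1.28 to 1.91; exact permutation p = 4.11e-05, 0.022 and 0.000123), which argues against a general loss. A difference in processing between the sets stays open, the labels name none, GC content was not tested, and no biological explanation was tested.

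Immediate early genes rose in the bound fraction, and neurons, in which these genes respond strongly, may have carried RNA over into it. Carry-over would raise them in bound by about the share of the unbound level that neuron markers keep. That share had an upper quartile of 0.339 in the waking and of 0.353 in the sleep deprivation comparison. It is no strict limit, since the highest neuron marker kept 0.754 and 0.725. The median ratio of the linear rise in bound over unbound was 0.515 for waking (bootstrap interval 0.214 to 0.844) and 0.71 for sleep deprivation (0.420 to 1.36), but these genes were picked by their rise in bound, which lifts the ratio. Over genes called in unbound it was 0.413 (0.139 to 0.624; 11 genes) and 0.573 (0.287 to 0.872; 8 genes), and over all with a rise in unbound 0.482 (0.243 to 0.660) and 0.588 (0.318 to 0.852), so carry-over stays open in both comparisons. Among the latter genes single ratios spread from -0.022 to 3.57 in waking and from -0.370 to 12.4 in sleep deprivation, and a response of astrocytes themselves remains a hypothesis.

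For the bound counts, 100 of the 462 splits of the 12 arrays were drawn per comparison, and 1 of 100, the real split, gave as many genes: 2039, 2597 and 1244, with a highest other of 7, 5 and 3. For genes changed alike (1059; highest other 1) and for bound against unbound (12627; highest other 0) it was again 1 of 100. If RMA was run separately for each group, only the real split keeps the runs whole. It would then give the most genes even without an effect of state or fraction. These 5 tests therefore cannot tell state or fraction from run. A split by animals 1 to 3 against 4 to 6 gave 5322, 4854 and 5100 genes, which points to the structure of the samples described above. Of the 32 splits that part each pair of equal replicate numbers, the real split gave the most, and the highest other was 1, 1 and 2. The limit set by possible separate runs holds for these splits too.

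In bound waking samples 1 array lay far from the other 5 for Dbp (gap over range 0.658, array 3), Homer1 (0.703, array 2) and Nfkbia (0.627, array 3), 3 of 171 groups tested, where chance gives such a value in about 1 in 20 groups. The response to waking differed between fractions in 1018 genes and that to sleep deprivation in 890. For Actg1 the difference (bound minus unbound) was -0.51 for waking and -0.54 for sleep deprivation, or -0.29 and -0.48 relative to the median of all genes, against which Actg1 lay lower in unbound as well (-0.18 and -0.16) without passing there. The rises of Dusp1 (-1.06) and Ppp1r3c (-0.90) in waking were smaller in bound, and those of Hif3a (2.26) and Tcim (4.16) after sleep deprivation larger, though the last 2 calls were lost in 9 and 10 of 32 alternatives.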

How the results depend on the processing

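The settings that use animals 1 to 3 or 4 to 6 of the bound arrays, and those that join several choices, were chosen after seeing the data. Comparisons are given in the order waking against sleep, sleep deprivation against sleep, sleep deprivation against waking, and genes changed alike, then the 3 unbound ones, then the difference between fractions for waking and for sleep deprivation. Of 7477 alternative values of 280 named gene values, 6271 kept their side of the threshold and, where they passed, their direction. A change of sign was counted only where the main or the alternative value passed. A further 1198 kept the direction without passing, 7 newly passed and 1 reversed: Dhx58, waking against sleep in bound, at 0.004 as fitted with the mean of probe sets (adjusted p = 0.994). The count of genes differing between fractions stayed within 1.5 times of its value except with every probe set.

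Without dim genes the counts were 142, 334, 76 and 70, unbound 130, 0 and 0 in limma, and 37 and 22 between fractions, where fewer genes were tested. Then 7, 2 and 1 lists passed for bound sleep deprivation against sleep, bound sleep deprivation against waking and the waking difference between fractions. With every probe set, more features were tested: 7102, 8301, 4913 and 3608, unbound 3101, 1241 and 650, between fractions 3934 and 3566, and 29781 for bound against unbound. With quantile normalization repeated, 1728 genes differed for sleep deprivation against sleep and 589 alike, unbound 0, 134 and 2. With centring 665 changed alike, unbound 0, 128 and 5. At 1.5-fold or more, 1067, 1396 and 677 differed. With bound-enriched genes only, 816, 1168, 519 and 447 differed.

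With the replicate number as a block 3064 and 1913 (sleep deprivation against waking) differed, 1656 alike, unbound 0, 0 and 0 in limma, and 7 lists passed for sleep deprivation against sleep, while 0, 0 and 0 bound lists passed with an estimated correlation as well. With animals 1 to 3 or 4 to 6 as a block the counts were 3385, 4102, 2164 and 1819. With animals 1 to 3 alone, where fewer arrays were used, they were 937, 1476, 585 and 409, and 4 lists passed for sleep deprivation against waking; with animals 4 to 6 alone 638, 1134, 143 and 280. With filter, repeated quantile normalization and this block together they were 690, 1005, 444 and 293, and 7, 7 and 2 lists passed, or 0, 2 and 0 with an estimated correlation as well. With filter and repeated quantile normalization the unbound counts were 0, 0 and 0 in limma (1711, 1959 and 1664 at an unadjusted p under 0.05) and those between fractions 21 and 30.

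With the mean of probe sets the unbound counts were 2031, 568 and 210, and 2 lists passed for bound waking; with an intensity trend they were 2935, 1259 and 622. With array weights the unbound count for sleep deprivation against waking was 4 and those between fractions were 1822 and 1546, and with the spread of all 24 arrays the unbound sleep deprivation counts were 999 and 800. With an estimated correlation in camera 0 lists passed in each of the 6 state comparisons and 10 for the fractions. With camera on ranks 1 and 2 lists passed between fractions. Except for the smaller or larger numbers of genes or arrays, the cause was not tested.

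With each array left out in turn, the bound counts ranged from 1706 to 2062, 2231 to 2604, 999 to 1277 and 883 to 1033, bound against unbound from 11899 to 12706, and between fractions from 502 to 1014 and 447 to 883, while the unbound counts were 0 to 0 in limma, the lone pool of a state being assumed to vary like the others. Lists ranged from 1 to 6, 3 to 5 and 1 to 2 in bound, 3 to 3, 2 to 6 and 0 to 1 in unbound, 15 to 16 for the fractions, and 0 to 1 and 0 to 0 between fractions. The highest list count for bound waking, 6, was without bound sleep array 4, and 2 lists passed for bound sleep deprivation against waking without sleep deprivation array 1 or 2, and for unbound sleep deprivation against sleep without unbound sleep deprivation pool 1. The list of fatty acid oxidation passed for the waking difference between fractions without bound sleep array 3, bound waking array 4, bound sleep deprivation array 6, unbound sleep pool 1 or unbound sleep deprivation pool 1 or 2. Of the bound calls, 76.6%, 70.9% and 79.6% lay below the median level, and detection above background was not measured.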

Other observations

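The comparisons of animals 1 to 3 with animals 4 to 6 in this part were chosen after the result was seen. All log2 differences and list medians in this part are as fitted, not relative to the median of all genes. Several long non-coding RNAs were low in the bound fraction, though not all, since Celrr was higher (log2 5.4 as fitted), and no list of them was tested. Malat1 (log2 -2.84 as fitted, adjusted p = 4.16e-06), Rian (-1.79), Snhg11 (-3.12) and Mir124a-1hg (-4.22), picked after their values were seen except for the list member Snhg11 and for Mir124a-1hg, were lower than in the unbound fraction, beside Meg3 and Miat.

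Some glucocorticoid-responsive genes rose more in animals 1 to 3 than in animals 4 to 6 after sleep deprivation, though none singly past a test of that difference, and no hormone level was among the data used here. In bound samples Fkbp5 was higher than in sleep by a log2, as fitted, of 4.02 in animals 1 to 3 and 1.94 in animals 4 to 6, Cdkn1a by 4.01 and 1.82, and Zbtb16 by 2.75 and 1.3, while Tsc22d3 (1.38 and 1.28) and Nfkbia (1.07 and 0.84) rose alike and Cebpd less in animals 1 to 3 (0.39 and 0.99). Outside the list, Tcim was higher by 5.33 and 2.10, Arc by 2.82 and 2.61, and Hif3a by 2.65 and 2.72. The list of 22 glucocorticoid-responsive genes differed between the sets (camera adjusted p = 8.17e-05, medians 0.70 and 0.32, lost at adjusted p = 0.0694 with an estimated correlation), but no gene of all tested passed limma singly, with 1099 at an unadjusted p under 0.05. In the unbound pools Fkbp5 was higher by 1.39 and 1.52 and Cdkn1a by 1.57 and 1.58. The meningeal list also differed between the sets after sleep deprivation (camera adjusted p = 0.011, lost at adjusted p = 0.759 with an estimated correlation), and so did 2 lists in waking, cholesterol biosynthesis (7.8e-05, medians -0.33 and 0.04) and ependymal and choroid plexus markers (2.48e-05, medians 1.11 and -2.86), both lost at adjusted p = 0.695 with an estimated correlation.

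The mean log2 level of the choroid plexus and ependymal markers varied widely between animals of 1 state. It ranged from 6.20 to 8.97 in bound sleep arrays, from 5.72 to 8.73 in waking and from 5.71 to 8.61 in sleep deprivation. Not every member varied so widely. In bound sleep arrays the SD (n = 6) was 2.49 for Kcne2 and 2.32 for Kl, but 0.27 for Foxj1 and 0.24 for Rarres2.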
